A study of Mus musculus with 85 samples.

How the data were processed

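Each of the 85 cells was sorted singly after collagenase dissociation, its RNA amplified, and the product hybridised to 1 Affymetrix whole-genome mouse array of 45101 probe sets. The deposited values are log2 expression values, which the authors made with GCRMA in the affy package, per the submitters' processing notes, with versions not given in the sources used here. GCRMA subtracts a background estimated from probe sequence and summarises the probes of each set. The deposited log2 values ran from 2.19 to 17.86, with most probe sets near the lower bound. A value over 5 was taken as above background, which 17.7% of all values were, and 0.999% of values lay between 5 and 6. The distributions were not equal between cells, so the values were not quantile-normalized as deposited, and no array was normalized again for the values in the report.

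Probe sets were named from a table of the platform's annotation. Of the 45101 probe sets 34958 had 1 gene symbol, 932 had several and 9211 were not listed, and only those with 1 symbol were used. Symbols were checked through the gene identifier against RefSeq genes of assembly GRCm38.p6, where 34754 matched and none needed another symbol. That table gave names only, and no coordinates are printed. Each of the 18194 genes was represented by the probe set with the highest mean over the 5 populations weighted equally, and 10695 genes were above background in at least 3 cells and counted as measured. For Runx1 and Hlf the number of cells above background on any probe set is also given. The 64 control probe sets were left out of all gene values. At least 1 of the control probe sets Dap 3' and Phe 3' held a value shared across arrays (12.64 and 9.50) in every array, and both did in 62 of the 85, so arrays look scaled to these controls, though not all in the same way. No source used here states that step.

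All arrays were compared with each other. Fetal liver HSC cells 20 and 21 correlated at r = 0.991 over all probe sets, with 6170 and 6020 probe sets above background and 5928 in common, and the next closest pair, E10.5 cluster cells 20 and 27, at 0.859. The pair was averaged and counted as 1 cell. The limit of 0.95 for this was chosen after the values were seen. No other cell was left out.

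The populations, the gene lists, the rule for named genes, the background threshold and most alternatives were fixed before the data were examined. Adjacent populations along the route from EC to HEC, E10.5 cluster, E12.5 cluster and fetal liver HSC were compared, and fetal liver HSC also with E10.5 cluster cells. Because each sample is 1 cell and no animal, litter or culture is named, a population counts as 1 sample and no test was made. A difference is that of the mean log2 values over cells. Named genes were the 10 with the largest positive and the 10 with the largest negative difference among genes above background in at least 50% of cells of the higher population, without genes of the sorting gates, and any member of the lists. For each list the median and mean difference over measured members and the number of members at or beyond 1 log2 unit each way were computed. The median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these cells and is not a test. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error over cells only, and the number of arrays limits precision.

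The 34 lists were pan-endothelial, arterial, venous and lymphatic, blood transcription factor, pan-hematopoietic, hemogenic endothelium, HSC-associated, fetal programme, imprinted, erythroid, megakaryocyte, myeloid, macrophage, lymphoid, mast-cell and basophil, germ-cell, mesenchymal and mural, hepatocyte, epithelial and urogenital, neural-crest, S-phase, G2/M, CDK-inhibitor, Notch-target, TGF-beta and BMP, interferon and MHC, Hox, glycolysis, oxidative-phosphorylation, ribosomal-protein, housekeeping, dissociation-stress, sorting-gate and sex-linked genes. Some lists had few measured members, such as 7 of 17 erythroid, 3 of 9 germ-cell and 1 of 8 neural-crest genes.

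The calculation was tested on simulated data made from the real cells, with 200 of 10695 genes shifted by 2 log2 units up or down. The median recovered shift was 2.01 for HEC minus EC, 2.00 for cluster minus HEC, 2.00 for E12.5 minus E10.5 cluster, 1.98 for HSC minus E12.5 cluster and 2.00 for HSC minus E10.5 cluster. Of the shifted genes 86.0, 82.0, 87.0, 89.5 and 92.5% reached a size of 1 in these comparisons. Of the unshifted genes 33.2, 30.3, 15.4, 22.6 and 11.7% reached it too, so a single gene of that size can come from the spread between cells, most of all where a population has 7 cells. Of 200 unshifted random lists 3.00, 6.50, 6.50, 0.500 and 3.50% fell outside the middle 95% of random medians, and of lists shifted by 1 unit 100, 98.5, 100, 100 and 100% lay above it. In the simulation each gene was redrawn on its own, and both populations came from the second one. It therefore held no correlation between genes and no depth differences between cells. How often lists of genes that vary together fall outside that range was not tested.

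Alternatives were a shift of each cell to an equal median of values above background, quantile normalization, thresholds of 4, 6 and 7, values at or under 5 set to 5, no filter on low values, the mean of a gene's probe sets, the brightest probe set without cross-hybridising designs, any probe set for shares, the median over cells, the log2 of the linear mean, the share of cells, removal of cells with fewer than 3932 probe sets above background (a limit set from the median over cells, which removed 1 EC), and each EC and HEC cell left out in turn. Added after the values were seen were cells with both control probe sets at the shared value, all cells but 6 whose genes went against their label, cells with at least 5000 probe sets above background, all cells but the 4 E12.5 cluster cells with the fewest probe sets above background, and the near-identical pair kept as 2 cells. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.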

Results

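Gene expression was measured in 85 single cells from mouse embryos, each hybridised to its own Affymetrix whole-genome mouse array with 45101 probe sets. The cells came from 5 sorted populations that lie along the route from vessel wall to blood stem cell. Endothelial cells (EC, 7 cells) and hemogenic endothelial cells (HEC, 7 cells, the endothelial cells from which blood arises) were taken at embryonic day (E) 10.5 from the caudal part of embryos carrying an eR1-GFP reporter, a Runx1 enhancer that drives GFP. EC were sorted as GFP-negative and HEC as GFP-positive, both CD31-positive and without Ter119, CD45 and CD41. Hematopoietic cluster cells, the blood cells that bud into the aorta, were sorted from wild-type embryos as c-Kit-positive, CD31-positive, CD45-positive and SSEA1-negative, at E10.5 from the caudal part (28 cells) and at E12.5 from the aorta-gonad-mesonephros region (16 cells). Hematopoietic stem cells (HSC) were sorted from wild-type E14.5 fetal liver as CD150-positive, CD48-negative, c-Kit-positive, Sca-1-positive, lineage-negative and Mac-1-positive. Of the 27 arrays of that population, cells 20 and 21 held almost the same values (r = 0.991 over all probe sets, against 0.859 for the next closest pair of arrays), so they were averaged and counted as 1 cell, which left 84 cells and 26 fetal liver HSC.

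No animal, litter or culture is named for any cell, so each population counts as 1 sample, and the data hold no replicate check on a difference between populations. Differences are therefore given by size only: a gene is called higher or lower when the mean log2 values of the populations differ by 1 or more. SDs are over cells and show cell-to-cell spread. EC and HEC share genotype, tissue and stage and differ in the GFP gate. The cluster populations share genotype and gate and differ in stage and tissue. The other comparisons differ in the sorting gate and in genotype, tissue or stage. In no comparison can the factors that differ be told apart from cell identity. The number of probe sets above background (a log2 value over 5) averaged 5905 ± 1447 (SD) in EC, 7712 ± 765 in HEC, 9943 ± 897 in E10.5 cluster cells, 7820 ± 1755 in E12.5 cluster cells and 6552 ± 884 in fetal liver HSC. The mix of sexes may differ too. Xist, a transcript of female cells, was above background in 3 of 7 EC and 4 of 7 HEC. It was in 14 of 28 E10.5 cluster cells, 6 of 16 E12.5 cluster cells and 1 of 26 HSC. In the same order a Y-linked gene was found in 0, 2, 12, 6 and 16 cells.

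Genes of the sorting gates checked the labels and are not results. Ptprc, which encodes CD45, was above background in 0 of 7 EC, 0 of 7 HEC, 26 of 28 E10.5 cluster cells, 15 of 16 E12.5 cluster cells and 22 of 26 fetal liver HSC. Kit was above background in 27 of 28 E10.5 cluster cells, 13 of 16 E12.5 cluster cells and 25 of 26 HSC, and in 3 of 7 cells of both endothelial populations. Pecam1, which encodes CD31, was found in 6 of 7 EC, 7 of 7 HEC, 20 of 28 E10.5 cluster cells and 11 of 16 E12.5 cluster cells, all gated as CD31-positive. Cd48 was found in 13 of 16 E12.5 cluster cells and 2 of 26 HSC, and Slamf1, which encodes CD150, in 10 of 26 HSC and 0 of 16 E12.5 cluster cells. The median difference of the 7 measured gate genes was -0.01 from EC to HEC, 2.34 from HEC to E10.5 cluster, -0.16 from E10.5 to E12.5 cluster, -1.77 from E12.5 cluster to HSC and -1.76 from E10.5 cluster to HSC. After quantile normalization the last 3 were 0.39, -0.66 and -0.44.

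In 6 cells the genes present went against the sorted identity. E10.5 EC cell 3 held the germ-cell genes Dppa3 (14.59) and Pou5f1 (13.96) and lacked Cdh5, which encodes VE-cadherin. E12.5 cluster cells 3, 6 and 10 held the macrophage complement gene C1qb at 15.69, 15.59 and 15.88. Fetal liver HSC cells 5 and 7 held Lyve1, a marker of sinusoidal and lymphatic endothelium, at 15.05 and 14.73. These cells stayed in the values given here, and each count that leads a comparison was also computed without them.

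**Figure D1:**
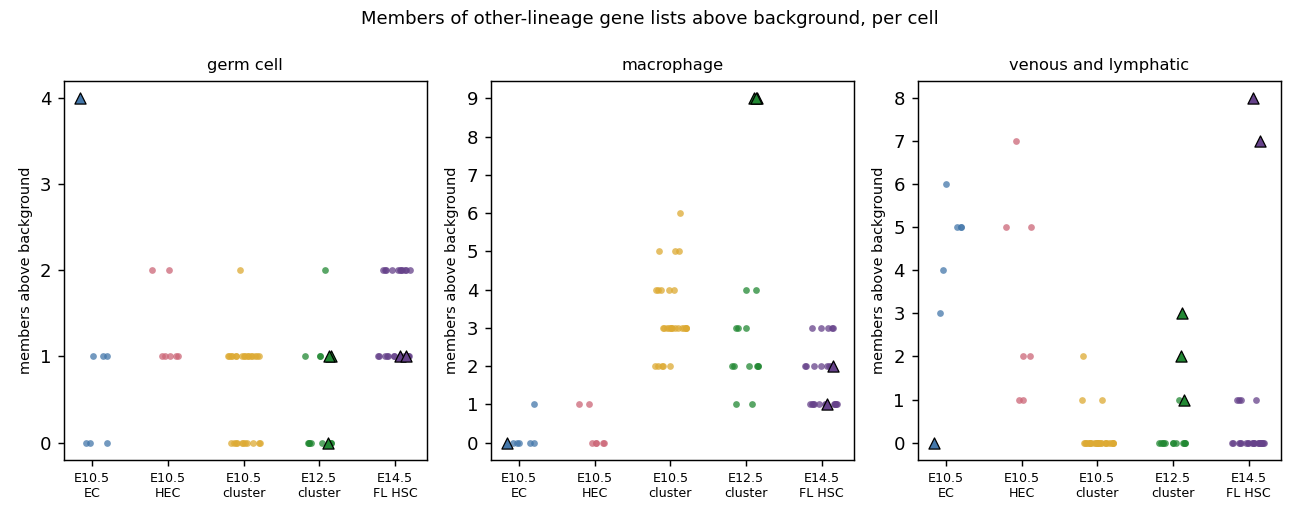
Number of genes above background per cell (vertical axis, count) for the germ-cell, macrophage and venous and lymphatic lists, by population (horizontal axis). Points are cells and triangles are the 6 cells whose genes went against their label. Germ-cell genes were counted over the 8 on the array and the other lists over their measured members. E10.5 EC cell 3 held 4 of 8 germ-cell genes, and E12.5 cluster cells 3, 6 and 10 held 9 of 9 measured macrophage genes each. HSC cells 5 and 7 held 8 and 7 venous and lymphatic genes.

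The comparison of HEC with EC asked which transcripts mark the endothelial cells that give rise to blood. Arterial genes were higher in HEC as a group. All 16 measured arterial genes were higher in HEC, with a median difference of 4.64, and none was lower. The median was 3.66 with cells shifted to an equal median signal and 3.28 after quantile normalization. It was 2.63 with the mean of a gene's probe sets. The mean over these genes was 8.59 ± 2.06 in 7 HEC and 4.33 ± 1.19 in 7 EC. In single cells 6 HEC lay between 7.17 and 10.60, while HEC cell 3, at 4.90 and with 4 of the 16 genes above background, lay within the EC, of which the highest was at 5.78. Gja4, which encodes the arterial gap-junction protein connexin 37, had the largest difference of any gene (8.69): it averaged 11.63 ± 4.25 and was above background in 6 of 7 HEC, against 2.94 ± 1.52 and 1 of 7 EC. Efnb2, the ephrin ligand of arterial endothelium, was higher by 5.45, the Notch ligand Dll4 by 4.79, the Netrin receptor Unc5b by 5.21 and the arterial transcription factor Sox17 by 4.66. All 4 measured Notch target genes were higher (median 5.28), with Hey1 at 5.85, Hey2 at 5.17, Nrarp at 5.39 and Hes1 at 2.65. Hey1 and Hey2 are also members of the arterial list. Hes1 was higher by 1.70 without HEC cell 6.

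Genes outside the arterial list also separated the populations. Mecom, a zinc-finger transcription factor needed by blood stem cells, was higher by 8.13 and above background in 6 of 7 HEC against 1 of 7 EC. Sox7, an endothelial transcription factor, was higher by 7.71, and Epas1, which encodes the hypoxia-responsive factor HIF-2α, by 7.47. Vegfc, a growth factor for lymphatic vessels, was higher by 7.90, and Lxn, a carboxypeptidase inhibitor, by 8.18 (7 of 7 HEC, 1 of 7 EC). Mob4 (7.75), the mitochondrial peptidase gene Immp1l (7.17), the polyamine acetyltransferase Sat1 (7.09) and the calcium-binding protein gene Rcn1 (6.94) completed the 10 genes with the largest differences. In the opposite direction, Aplnr, the apelin receptor of venous endothelium, was lower in HEC (-6.80, in 2 of 7 HEC and 6 of 7 EC). The potassium-channel subunit gene Abcc9 differed by -4.71, the Notch ligand Dll1 by -4.49 (0 of 7 HEC, 4 of 7 EC), the lipid phosphatase Mtm1 by -4.80 and Mmrn1, which encodes multimerin 1, by -4.13. Of the 8 measured venous and lymphatic genes, 2 were higher and 2 lower (median -0.03, mean -0.97), with Nrp2 at -2.79, Flt4 at -0.99 and Nr2f2 at 0.52. Without EC cell 3, 1 was higher and 3 were lower (median -0.35, percentile 0.73 among random lists), and the median over all cells was -1.17 after quantile normalization. HEC differed from each other: the mean over these genes was 8.69, 10.17 and 6.69 in HEC cells 3, 6 and 7 and between 3.19 and 4.17 in the other 4.

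Blood transcription factors were present in part. Of 14 measured members, 6 were higher in HEC and 1 was lower, with a median of 0.73 and a mean of 1.91. Hhex was higher by 6.38, Lyl1 by 4.82, Lmo2 by 4.75 and Gata2 by 4.67, while Runx1, the regulator of blood emergence whose enhancer drives the sorted reporter, was above background in 0 of 7 HEC and 0 of 7 EC on any of its 6 probe sets, a count that allows a share of up to 41.0% in each (exact 95% interval). Gfi1 was also found in 0 of 7 cells of both. Myb was above background in 1 EC, cell 3, and in 0 of 7 HEC (difference -1.49, and -0.01 without that cell). Of 18 pan-hematopoietic genes 5 were higher (median 0.05, and -0.33 after quantile normalization), among them the adhesion receptor Cd44 (6.08). Myeloid genes (0 of 11 higher or lower), erythroid genes (0 higher, 1 lower of 7) and megakaryocyte genes (1 higher of 10) had medians of -0.05, -0.02 and -0.04. Of 26 genes associated with HSC, 17 were higher in HEC and 1 lower (median 1.39), including the protein C receptor Procr (4.98), Fgd5 (4.95) and the cell-cycle inhibitor Cdkn1c (5.46). Of 11 hemogenic endothelium genes, 6 were higher and 1 lower (median 1.73). This list adds no gene to the others. It shares 7 members with the blood transcription factors and Adgrg1 and Mecom with the HSC-associated list. Cd44 is also in the pan-hematopoietic and Sox17 in the arterial list. Shifting cells to an equal median signal moved every difference in this comparison by -0.97, which left 0.41 for the HSC-associated and 0.76 for the hemogenic list. After quantile normalization these were 0.92 and 0.00.

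Of 25 pan-endothelial genes 22 were higher in HEC (median 2.66, mean per cell 11.22 ± 0.64 against 8.57 ± 2.79), among them Cldn5 (4.45), Mmrn2 (4.43) and Cdh5 (2.47). The median was 1.69 with shifted cells and 1.53 after quantile normalization. Without EC cell 3, 16 were higher and 1 lower (median 1.81, percentile 67.2 among random lists), and Cdh5 differed by 1.09. BMP and TGF-beta pathway genes were higher in 12 of 14 cases (median 3.12, with 2.15 and 1.65 under these scalings), with the inhibitory Smad6 at 4.37, the BMP target Id1 at 3.45 and the receptor Tgfbr3 at 5.80. The median over all 10695 measured genes was itself 0.82 higher in HEC, and -0.15 or 0.00 after the alternative scalings, so lists are set against 10000 random lists of the same expression level. The arterial, Notch-target and BMP lists stood at percentiles of 100, the blood transcription factors at 9.45, the HSC-associated list at 87.1, S-phase genes (median 0.35) at 0.04 and G2/M genes (median 0.44) at 0.76. The S-phase median was -0.62 with shifted cells and -0.81 after quantile normalization, and the G2/M median -0.54 and -0.53. The median of the blood transcription factors was -0.24 when cells were shifted to an equal signal and 1.74 without HEC cell 7.

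**Figure D2:**
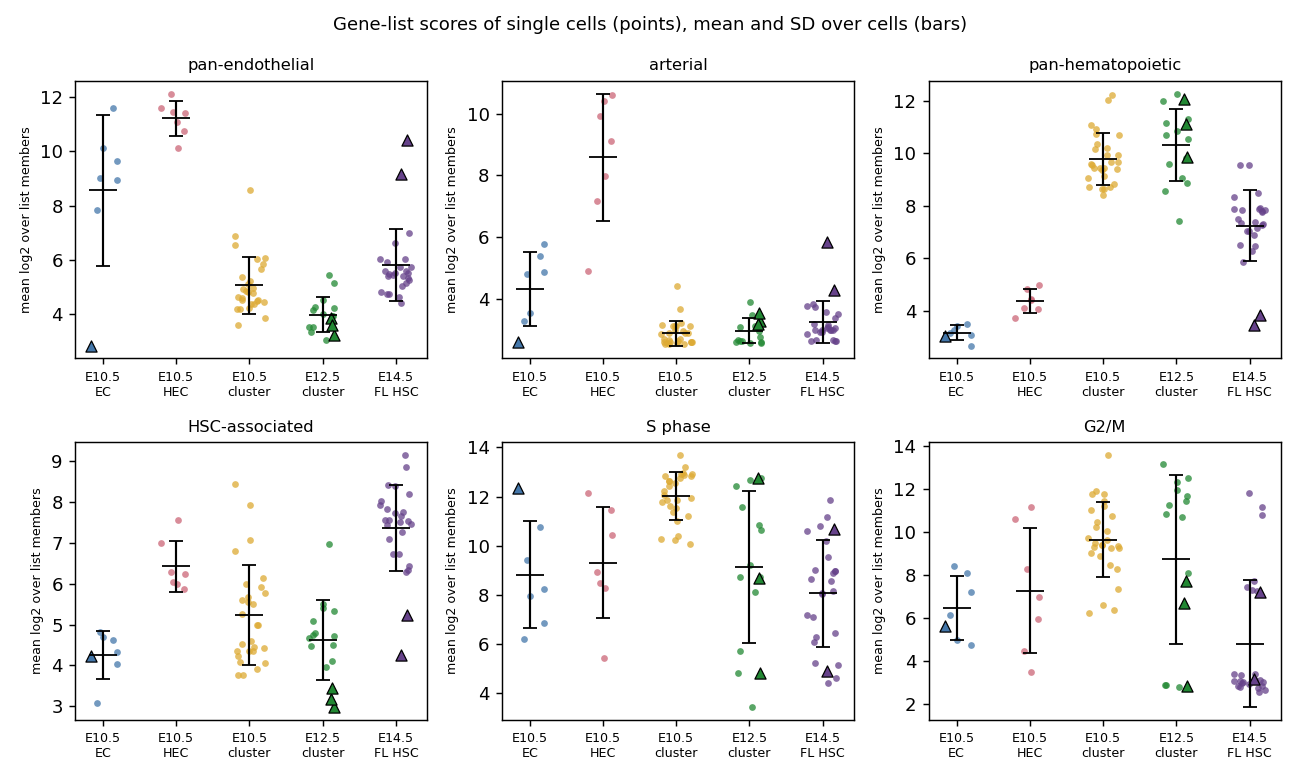
Gene-list scores per cell (vertical axis, mean log2 value over list members) for 6 lists by population (horizontal axis). Points are cells, triangles the 6 cells whose genes went against their label, and bars the mean and SD over cells. The pan-endothelial score averaged 11.22 in HEC and 5.06 in E10.5 cluster cells, and the pan-hematopoietic score 4.37 and 9.78.

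The comparison of E10.5 cluster cells with HEC asked what is lost and gained when cells leave the endothelium. Most endothelial transcripts were lower in cluster cells, and most blood transcripts were higher. Of 25 pan-endothelial genes 24 were lower in cluster cells (median -6.39, mean per cell 5.06 ± 1.05 in 28 cluster cells and 11.22 ± 0.64 in 7 HEC) and 1 was higher, and all 16 arterial genes (median -5.73), 8 of 8 venous and lymphatic genes (median -2.91) and 4 of 4 Notch targets (median -5.92) were lower. The tight-junction gene Cldn5 was above background in 0 of 28 cluster cells and 7 of 7 HEC (-10.20), Cdh5 in 5 of 28 and 7 of 7 (-9.60), Mmrn2 in 2 of 28 and 7 of 7 (-10.76), and Notch4 in 1 of 28 and 7 of 7 (-10.14). Epas1 (-10.83), the basement-membrane collagen gene Col4a2 (-10.34), the fibrillar collagen gene Col5a2 (-10.16), Sox7 (-9.89), the semaphorin and VEGF receptor Nrp1 (-9.88) and the ephrin gene Efna1 (-9.82) were also among the 10 genes lowest in cluster cells. Egfl7, a secreted endothelial protein also made by blood progenitors, kept a mean of 9.88 ± 1.65 and was found in 28 of 28 cluster cells, against 12.19 ± 1.58 in HEC (-2.31).

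Of 18 pan-hematopoietic genes 17 were higher in cluster cells (median 4.92, mean per cell 9.78 ± 0.98 against 4.37 ± 0.45) and none was lower. Over the alternative settings that median ranged from 2.97 to 6.28. The signalling adaptor Plek had the largest difference among genes higher in cluster cells (10.86): it averaged 13.39 ± 1.15 in 28 of 28 cluster cells and 2.53 ± 0.21 in HEC, where 0 of 7 cells had it. The actin regulator Coro1a was higher by 10.36 and the integrin activator Fermt3 by 9.67. Myb, a transcription factor of definitive blood cells, was found in 28 of 28 cluster cells and 0 of 7 HEC (9.53), Ikzf1 in 28 of 28 and 1 of 7 (8.52), Spi1 in 25 of 28 and 0 of 7 (5.68), Gfi1b in 17 of 28 and 0 of 7 (4.08) and Runx1 in 20 of 28 and 0 of 7 (3.73). Gata2 (-0.62) and Hhex (0.34), already high in HEC, differed by less than 1, and Lmo2 differed by -1.24 (-0.95 without HEC cell 3). Of the 14 blood transcription factors 7 were higher and 1 was lower, with a median of 0.97 (1.48 with shifted cells and 0.58 after quantile normalization) and a mean of 2.64. Tal1, a member of both this list and the pan-endothelial list, was higher by 1.07, but the value depended on single cells. It was 1.66 without HEC cell 1, 1.76 without cell 3, 0.08 without cell 5, 0.04 without cell 7, and -1.51 among cells with both control probe sets at the shared value.

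Lineage genes appeared in cluster cells. Myeloid genes were higher in 9 of 11 cases (median 3.99, and 2.11 after quantile normalization), with the granule genes Mpo (27 of 28 cells, 9.68) and Prtn3 (27 of 28 cells, 9.50), the cytokine receptor chain Csf2rb (6.12) and the Fc receptor Fcgr3 (6.84). Erythroid genes were higher in 5 of 7 cases (median 2.98), with the transferrin receptor Tfrc at 7.18 and the transcription factor Nfe2 at 8.24, and megakaryocyte genes in 6 of 10 (median 1.24), with the integrin Itgb3 at 5.35. Of the 15 erythroid genes on the array only these 7 were measured. Gata1, among them, differed by -0.03 with the median over cells. The serine-synthesis enzyme Phgdh was higher by 10.78 and found in 28 of 28 cluster cells and 0 of 7 HEC, and the granule proteoglycan Srgn, the adenylate cyclase Adcy7 and the phospholipase Pla2g4a were higher by 8.80, 9.54 and 9.02. S-phase genes were higher in 14 of 16 cases (median 2.66, percentile 100), with the replication helicase genes Mcm3 at 4.25 and Mcm5 at 3.81, and G2/M genes in 17 of 20 (median 2.02, percentile 88.7, and 1.25 after quantile normalization), with Ccnb2 at 4.95. Mcm5 was higher by 2.44 without HEC cell 5.

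Genes associated with HSC were split. Of 26 measured members 5 were higher in cluster cells and 14 lower (median -1.08, percentile 0), with a median of -0.57 when cells were shifted to an equal signal. Mecom differed by -8.54 and was found in 3 of 28 cluster cells against 6 of 7 HEC, the transglutaminase Tgm2 differed by -7.61, Fgd5 by -5.85 and Procr by -5.38 (3 of 28 and 5 of 7 cells). Meis1, a homeobox cofactor of stem cells, was higher by 6.34 (25 of 28 cells), the stem-cell niche ligand Angpt1 by 6.49 and the receptor gene Adgrg1 by 5.76. Hlf, a transcription factor linked to HSC, was above background in 5 of 28 cluster cells (17.9%, exact 95% interval 6.06 to 36.9%, which covers counting error over cells only) and 1 of 7 HEC (difference 0.54). On either of its 2 probe sets Hlf was found in 8 of 28 cluster cells and 1 of 7 HEC. Imprinted genes were lower in 9 of 10 cases (median -5.94), led by Mest (-11.37), which had the lowest difference of any gene, with Plagl1 at -9.75 and the growth factor Igf2 at -8.01. The median over all genes was 0.71 higher in cluster cells, and 1.22 or 0.17 under the alternative scalings. HEC came from reporter embryos and cluster cells from wild-type embryos.

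**Figure D3:**
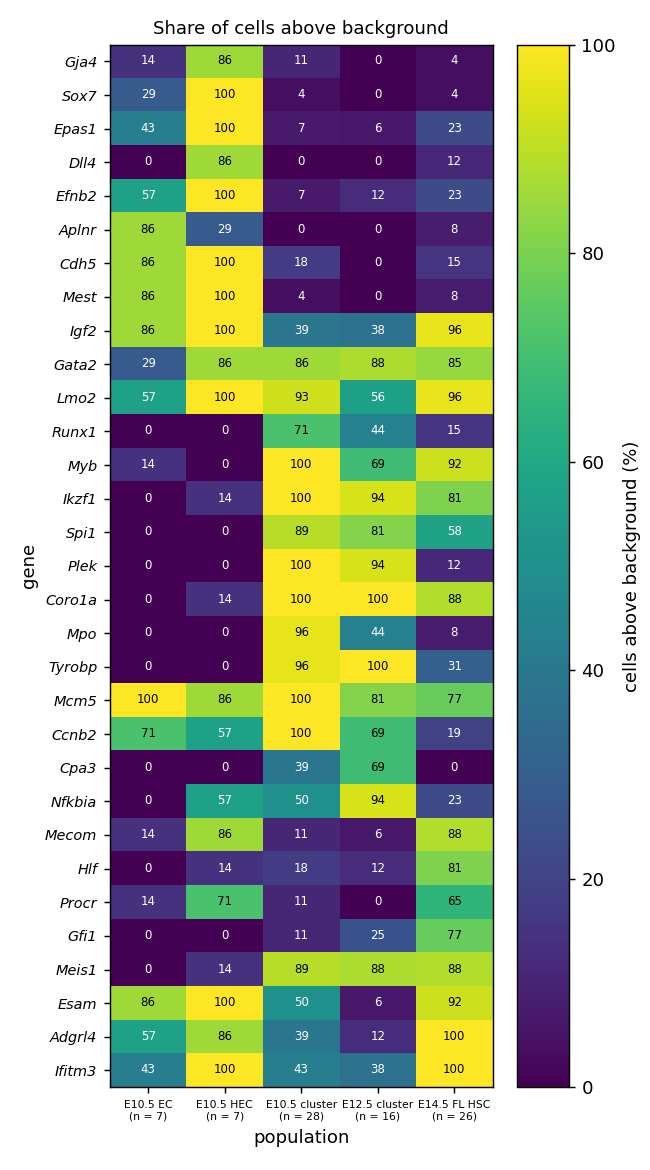
Share of cells above background (colour and printed number, percent) for 31 genes (vertical axis) in the 5 populations (horizontal axis, with the number of cells). Mecom was above background in 85.7% of HEC, 10.7% of E10.5 cluster cells and 88.5% of fetal liver HSC.

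The comparison of E12.5 with E10.5 cluster cells asked how cells of one gate differ between stages and sites. E12.5 cells held less of the S-phase genes, most of all 4 cells with few probe sets above background. Mast-cell and basophil genes, of which 3 of 7 were measured, were higher in 2 cases. S-phase genes were lower in 15 of 16 cases (median -2.87, percentile 0, mean per cell 9.12 ± 3.09 in 16 E12.5 and 12.02 ± 0.97 in 28 E10.5 cells), with Rrm2, a ribonucleotide reductase subunit, at -4.56, Mcm7 at -3.56 and Mcm3 at -2.89. Cells 1, 3, 7 and 11, with the fewest probe sets of the 16 (4137 to 6045), had S-phase scores of 3.43 to 5.73, and the other 12 averaged 10.60 ± 1.82. Without these 4 cells 10 of 16 S-phase genes were lower (median -1.32), with Rrm2 at -2.83, Mcm7 at -1.89 and Mcm3 at -0.90. G2/M genes had no settled direction (median -0.88, 3 higher and 9 lower of 20), and without the 6 doubted cells 5 were higher and 8 lower (median -0.43). The G2/M median over all cells was -0.35 after quantile normalization. Cells 1, 3, 7 and 11 had at most 1 of the 20 genes above background and the other 12 at least 11, with a mean score of 10.68 ± 2.06 in these 12 against 9.63 ± 1.73 at E10.5. Without the 4 cells 11 G2/M genes were higher and 2 lower (median 1.29). The neutrophil proteinase gene Prtn3 was lower (-5.63, in 7 of 16 E12.5 and 27 of 28 E10.5 cells), as was Mpo (-4.66), while the myeloid list as a whole had a median of -0.48, with 2 higher and 5 lower of 11 (-0.15 after quantile normalization and -0.72 without the doubted cells). The non-coding host RNAs Dancr (-6.19), Snhg4 (-6.06) and Snhg12 (-5.68), the chromatin protein gene Psip1 (-5.51), the lactate transporter Slc16a1 (-5.45) and the asparagine synthetase Asns (-5.25) were among the 10 lowest.

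Of the blood transcription factors 9 of 14 were lower and 2 higher (median -1.59, percentile 15.4, -0.55 after quantile normalization and -0.78 without cells 1, 3, 7 and 11), with Lmo2 at -3.72 and Myb at -3.18. Erythroid genes were lower in 4 of 7 cases and higher in none (median -1.12, percentile 7.75), with Nfe2 at -4.91 and Tfrc at -2.57, and Itgb3 of the megakaryocyte list was found in 1 of 16 E12.5 and 22 of 28 E10.5 cells (-4.88). Without cells 1, 3, 7 and 11 the erythroid median was -0.66 and Tfrc differed by -1.43. Without the 6 doubted cells that median was -0.65, after quantile normalization it was -0.52, and with the median over cells in place of the mean it was 0.01. Of 26 HSC-associated genes 1 was higher and 5 lower (median -0.28, percentile 96.7), including Adgrg1 (-3.71), while Meis1 (0.03), Mecom (-0.41) and Hlf (-0.55) differed by less than 1. Hlf was above background in 2 of 16 E12.5 cluster cells (12.5%, exact 95% interval 1.55 to 38.3%). The HSC-associated median was 0.24 after quantile normalization and 0.03 without the doubted cells, where 4 genes were higher and 6 lower, so its direction depended on the setting. Of 25 pan-endothelial genes 9 were lower and none higher (median -0.60, against -1.17 for random lists, percentile 97.0), with the angiopoietin receptor Tek at -3.35, the junction gene Esam at -2.84 and Cd34 at -2.77. That median was -0.05 after quantile normalization and 0.01 with the median over cells. Without cells 1, 3, 7 and 11 it was -0.52, against -0.59 for random lists (percentile 58.6). The HSC-associated median was then -0.16 (percentile 86.5), so both placements depended on these cells.

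Nfkbia, an inhibitor of NF-kappaB, was the gene highest in E12.5 against E10.5 cluster cells (5.45, in 15 of 16 and 14 of 28 cells), followed by Tnfaip3, another inhibitor of that pathway (4.96). Glipr1 (4.70), Basp1 (4.49), the lysosomal activator Gm2a (4.47), the receptor Notch2 (3.83) and the lectin gene Lgals1 (3.82) were also higher. The mast-cell protease Cpa3 was higher by 4.36 and found in 11 of 16 E12.5 and 11 of 28 E10.5 cells. The median of the 3 mast-cell and basophil genes was 2.63, with the granzyme Gzmb at 2.63. Macrophage genes had a median of 1.43 with 5 of 9 higher, of which C1qb differed by 3.04, but without the 6 doubted cells 1 was higher, 2 were lower and the median was -0.24. Mrc1, the macrophage mannose receptor, was higher by 1.88 and differed by -0.24 without those cells. Pan-hematopoietic genes were higher in 5 of 18 cases and lower in 1 (median 0.37, and 1.18 after quantile normalization). The median over all genes was -0.66 in this comparison, and -0.70 or -0.02 under the alternative scalings.

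The comparison of fetal liver HSC with E12.5 cluster cells asked which transcripts mark the transplantable stem cell at the site where it expands. HSC held more of the stem-cell genes than cluster cells and less of the G2/M genes. Of 26 HSC-associated genes 19 were higher in HSC and none lower (median 2.36, against -0.57 for random lists, percentile 100), and the mean per cell was 7.36 ± 1.06 in 26 HSC and 4.62 ± 0.99 in 16 cluster cells. On average 7.125 of the 26 genes were above background in E12.5 cluster cells. Most could therefore not fall as the matched genes could, which limits what the percentile shows. Mecom had the largest difference among genes higher in HSC (7.41): it averaged 10.18 ± 3.25 in HSC and was found in 23 of 26 cells, against 2.76 ± 1.67 and 1 of 16 E12.5 cluster cells. Hlf was higher by 5.27 and found in 21 of 26 HSC (80.8%, exact 95% interval 60.6 to 93.4%), or in 22 of 26 on either probe set. Procr was found in 17 of 26 HSC and 0 of 16 cluster cells (5.69), Pdzk1ip1 in 20 of 26 and 1 of 16 (4.77), Hoxa9 in 19 of 26 and 2 of 16 (4.55), Mycn in 20 of 26 and 4 of 16 (4.57) and Gimap6 in 26 of 26 and 8 of 16 (4.27). The transcriptional repressor Gfi1, which restrains stem-cell division, was found in 20 of 26 HSC and 4 of 16 cluster cells (5.29).

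Some endothelial genes were higher in HSC than in cluster cells. Of 25 pan-endothelial genes 17 were higher and 1 lower (median 1.52, percentile 100), and without the 6 doubted cells 12 were higher and none lower (median 0.86). On average 5.06 of the 25 were above background in E12.5 cluster cells. Most could therefore not fall as the matched genes could, which limits what the percentile shows. Esam, a junction protein also found on stem cells, was found in 24 of 26 HSC and 1 of 16 cluster cells (6.78), and Egfl7 in 26 of 26 and 7 of 16 (4.44). Adgrl4, an adhesion receptor of endothelium, was higher by 7.41, the receptor Calcrl by 5.84 and the G-protein subunit Gng11 by 5.27. Cdh5 was found in 4 of 26 HSC, 2 of them cells 5 and 7, and 0 of 16 cluster cells (1.39), and Cd93 was higher by 3.07 (1.99 without cluster cells 1, 3, 7 and 11). The collagen gene Col4a2 was found in 18 of 26 HSC (5.28). With the median over cells in place of the mean the pan-endothelial median was 0.07. Ifitm3, an interferon-induced membrane protein, was found in 26 of 26 HSC and 6 of 16 cluster cells (7.32).

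All 20 G2/M genes were lower in HSC (median -3.87, percentile 0, mean per cell 4.78 ± 2.95 against 8.72 ± 3.93), with the survival and spindle gene Birc5 at -5.86, Top2a at -5.23 and Mki67 at -4.64. Of the 26 HSC 18 had at most 2 of the 20 genes above background and 8 had at least 12, while 12 of the 16 E12.5 cluster cells had at least 11 and 4 at most 1. Without these 4, cluster cells 1, 3, 7 and 11, the G2/M median was -5.91 and Mki67 differed by -7.04. With all cells the G2/M median was -2.92 after quantile normalization and -7.61 with the median over cells. S-phase genes stood near random lists, lower in 9 of 16 cases (median -1.26, percentile 55.3, and -0.26 after quantile normalization), in 7 without the doubted cells (median -0.81) and in 13 without the 4 cluster cells (median -2.42, percentile 9.26). Control probe sets for RNA differed between the same populations. The 3' minus 5' difference of Actb was 3.96 ± 2.31 in HSC and 2.65 ± 1.09 in E12.5 cluster cells, that of Gapdh 2.64 ± 1.88 and 1.91 ± 1.10, and the level of the Actb 3' probe set 10.03 ± 1.18 and 12.62 ± 1.56. All 18 pan-hematopoietic genes were lower (median -2.26, and -1.27 after quantile normalization), led by Plek (-9.42, in 3 of 26 HSC and 15 of 16 cluster cells), with Coro1a at -2.41. Without the doubted cells 15 of the 18 were lower. Fc-receptor genes were among the lowest, with Fcgr3 at -8.74 (0 of 26 HSC), the signalling chain Fcer1g at -7.33 and the adaptor Tyrobp at -7.43, and Cpa3 was found in 0 of 26 HSC (-7.05). The 3 mast-cell and basophil genes were all lower (median -2.57). Macrophage genes (median -2.01, 7 of 9 lower) and myeloid genes (median -1.12, 6 of 11 lower) both had a median of 0.02 without the doubted cells, while Mpo differed by -4.46. All 15 genes of the dissociation-stress list were lower in HSC (median -3.84, percentile 0), with Hspa1a at -7.06, Jun at -6.29 and Fos at -5.55, and Nfkbia differed by -7.44. Of the blood transcription factors 6 were higher and 5 lower of 14 (median 0.46, 1.45 after quantile normalization and -0.33 without cluster cells 1, 3, 7 and 11), with Lmo2 at 4.21, Spi1 at -2.06 and Runx1 at -1.41. Under quantile normalization Spi1 differed by -0.81 and Runx1 by -0.14. The direction for Runx1 depended on the probe set. On another one its means were 5.72 in HSC (12 of 26 cells above background) and 5.54 in E12.5 cluster cells (7 of 16). The median over all genes was -0.54 in this comparison, and -0.49 or 0.03 under the alternative scalings.

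**Figure D4:**
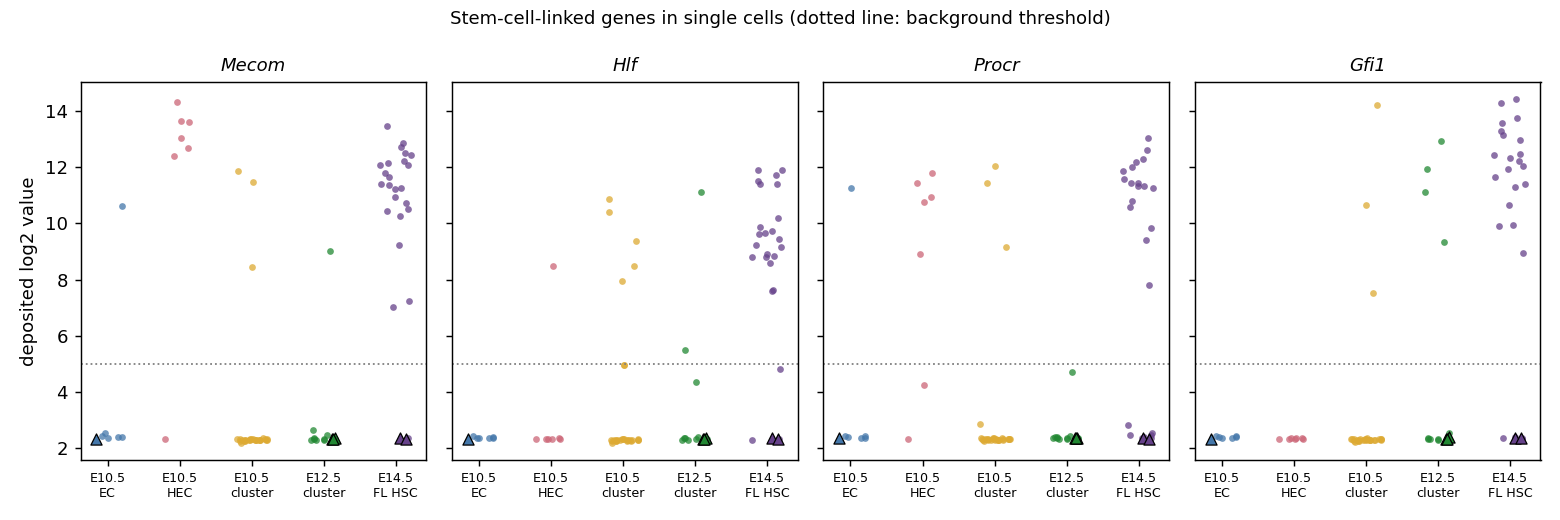
Deposited log2 value (vertical axis) of Mecom, Hlf, Procr and Gfi1 in single cells of the 5 populations (horizontal axis). Points are cells, triangles the 6 cells whose genes went against their label, and the dotted line the background threshold of 5. Mecom lay above the line in 6 of 7 HEC and 23 of 26 fetal liver HSC, and Gfi1 in 0 of 7 HEC and 20 of 26 fetal liver HSC.

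The comparison of fetal liver HSC with E10.5 cluster cells set the ends of the blood part of the route side by side. Of 26 HSC-associated genes 16 were higher in HSC and 2 lower (median 1.99, percentile 100, and 3.38 after quantile normalization). On average 9.54 of the 26 genes were above background in E10.5 cluster cells. Most could not fall as the matched genes could, which limits what the percentile shows. Mecom (7.0, in 23 of 26 HSC and 3 of 28 cluster cells) and Gfi1 (6.67, in 20 of 26 and 3 of 28) had the largest differences among genes higher in HSC. Hlf was higher by 4.72, Procr by 4.94, Pdzk1ip1 by 4.78, Hoxa9 by 4.40 and Ifitm1 by 3.31, whereas Meis1 (0.03) and Angpt1 (0.55) differed by less than 1 and Rbpms differed by -2.29. Ifitm3 (6.44), Cd24a (5.85), Adgrl4 (5.82), the interferon-inducible gene Mndal (5.42) and the chromatin remodeller Chd3 (5.20) were among the 10 highest. Of the 21 HSC with Hlf 21 also held Mecom and 15 held Procr, while 23 and 17 of all 26 HSC held these genes. Among E10.5 cluster cells 5 held Hlf and 3 held Mecom, with 1 cell holding both.

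Cycling genes were lower in HSC than in E10.5 cluster cells, with 19 of 20 G2/M genes (median -5.08) and 15 of 16 S-phase genes (median -4.13) lower and none higher, at percentiles of 0. After quantile normalization these medians were -3.43 and -2.27. Birc5 (-8.07), Rrm2 (-7.83), Trip13 (-7.63) and Ccnb2 (-7.55) were among the 10 lowest, beside Plek (-9.95), Mpo (-9.12) and Tfrc (-7.81). The 3' minus 5' difference of Actb was 2.64 ± 1.39 and that of Gapdh 1.82 ± 1.39 in E10.5 cluster cells, against 3.96 ± 2.31 and 2.64 ± 1.88 in HSC. Pan-hematopoietic genes were lower in 14 of 18 cases (median -2.49, percentile 26.7, and -0.75 after quantile normalization) and blood transcription factors in 9 of 14 (median -1.06, but 0.72 after quantile normalization). Random lists matched to the transcription factors had a median of -2.31, which placed them at percentile 99.0, and without the doubted cells 1 was higher and 4 were lower (median -0.64). Myeloid genes were lower in 7 of 11 cases (median -1.83, and -0.72 after quantile normalization), with Fcgr3 at -6.83 and Csf2rb at -4.23. Erythroid genes were lower in 5 of 7 cases and higher in 1 (median -1.43, percentile 12), with Gata1 (0 of 26 HSC, 10 of 28 cluster cells) at -2.97, Klf1 at -2.13 and Car2, which was higher, at 1.28. The erythroid median was 0.04 with the median over cells and 0.05 without a filter on low values, so its direction depended on the setting. Runx1 differed by -2.76 on its brightest probe set, by 0.61 after quantile normalization and by 0.04 without the 6 doubted cells. Without those cells another of its 6 probe sets became the brightest. On any probe set Runx1 was found in 24 of 28 cluster cells, 10 of 16 E12.5 cluster cells and 15 of 26 HSC. Pan-endothelial genes were higher in 9 of 25 cases and lower in 2 (median 0.40, against -2.24 for random lists, percentile 100), with Esam at 3.94 and Cdh5 at 0.22. On average 9.07 of the 25 were above background in E10.5 cluster cells, so most could not fall as the matched genes could. That percentile therefore does not show a gain in HSC. The pan-endothelial median was 1.47 after quantile normalization and -0.04 without the doubted cells. The median over all genes was -1.29 in this comparison, and -1.28 or -0.02 under the alternative scalings.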

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

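The tests on E10.5 EC cell 3 were chosen after its values were seen. In the populations of 7 cells a value was singled out by Dixon's 95% limit. That limit is passed when the gap to the nearest of the other cells is large against the whole range. For normally distributed values chance does this in about 1 in 20 groups. Many values here lie either at background or well above it, so 1 cell above background among 7 is easily singled out. Hlf in HEC cell 2, for example, had a gap of 0.993 of the range. The rate of 1 in 20 therefore does not apply to the counts given here. Of 210 groups of values 47 were singled out. Single genes with all cells of a population at background were skipped, a choice made after the values were seen; with them included the count was 58 of 258.

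EC cell 3 held 10 of the genes singled out. It was low for Aplnr (2.32), Cdh5 (2.32), Col4a2 (2.46), Igf2 (3.0), Mest (2.32), Mmrn1 (2.32) and Plagl1 (2.33), and high for Fermt3 (9.10), Myb (12.90) and Smad6 (7.12). Its epithelial and urogenital score was 5.40, with 1 gene of that list above background. It also held Dppa3 (14.59), Pou5f1 (13.96), Ifitm3 (15.54) and Prdm1 (9.98), the first of which is a gene of primordial germ cells, which express c-Kit and pass through the caudal embryo at this stage. It had 4 of the 8 germ-cell genes on the array above background against at most 2 in any other cell, so a germ cell that passed the gate is a candidate explanation. Ddx4 (2.32), Dazl (2.32), Sycp3 (2.32) and Dppa5a (2.64) were at background in it. Ifitm3 and Prdm1 were also above background in 2 and 1 of the other EC, and Dppa3 and Pou5f1 in none. The EC gate held no SSEA1 exclusion, while the CD31 gate does not remove germ cells that carry CD31. RNA of a germ cell mixed with that of an endothelial cell is argued against, since 1 of 25 pan-endothelial genes was above background in this cell and 19 to 24 were in the other EC. The cell was picked for germ-cell genes without endothelial genes, so the germ-cell and endothelial counts restate that choice. They are not independent tests. A cell of an earlier pluripotent type or a mislabelled cell stays open, and no biological difference among endothelial cells was tested.

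In the other EC, cell 1 was high for Adgrg1 (9.08), Arhgdib (8.99), Procr (11.25) and Srgn (11.48). Cell 2 was high for Gja4 (6.39) and Vegfc (9.89), and cell 4 for Hey2 (9.21) and Mecom (10.62). Cell 5 was high for Lxn (9.90) and low for Maco1 (2.77). Cell 7 was high for Laptm5 (6.12) and Lyl1 (7.04), for the mesenchymal and mural score (3.12) and for the hepatocyte score (4.99). It had 0 mesenchymal and mural genes and 1 hepatocyte gene above background, so these scores do not show such an identity.

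Among HEC, cell 2 was high for Coro1a (7.92), Hlf (8.47) and the lymphoid (3.96), hepatocyte (4.08) and epithelial and urogenital (4.79) scores, and low for Fgd5 (8.99). Each of these scores rested on 1 gene above background. Cell 3 was high for Abcc9 (12.83), Fermt3 (5.04) and Pank1 (11.96), and low for Gja4 (2.31), Mecom (2.31), Nrarp (2.31), Sat1 (2.52) and Vegfc (2.34). Cell 4 was low for Egfl7 (8.78), and cell 7 high for Ikzf1 (9.57). Cell 6 was low for Epas1 (11.68), Gata2 (3.02), H2-K1 (3.10) and Mmrn2 (11.91), and high for Meis1 (6.15) and the mesenchymal and mural score (5.21). That score rested on 1 gene above background.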

How the results depend on the processing

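No paired analysis was possible because the cell numbers only count the cells of a population and no result comes from a test. The settings that use control probe sets, the 6 doubted cells, 5000 probe sets, the 4 E12.5 cells with fewest probe sets or the near-identical pair were chosen after the results were seen. Of 352 alternative values of the 19 results that answer the comparisons 331 stayed and 18 moved further. Another 3 changed sign from a size of 1 or more. To stay meant to lie within the spread over cells or, for the Hlf shares, within their interval. Differences taken on the share of cells are in percentage points, so the spread was not applied to them. They stayed if they kept their sign or if the main difference was under 1. With smaller differences counted too, and differences on the share of cells left out, 9 of 338 changed sign. Of these, 1 came under a shift of cells that moves every gene of a comparison alike and so says nothing of that list against other genes. Of 4418 values of 243 named genes and other differences 4217 stayed, 180 moved and 21 changed sign from such a size (47 of 4175 with smaller ones). Signal over background limits genes near a log2 value of 5, and thresholds of 4, 6 and 7 bear on shares and on which list members are measured. Except where a reason is given, the cause was not tested.

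For HEC minus EC, the blood transcription factor median was -0.24 with cells shifted to an equal median, 1.81 without cross-hybridising probe sets, 2.07 in cells with both controls at the shared value, and 0.65 to 1.74 with 1 cell left out in turn. The arterial median was 2.63 with the mean of a gene's probe sets. For cluster minus HEC, the pan-hematopoietic median was 4.04 with quantile normalization, 3.6 with values at or under 5 set to 5, 2.97 with the mean of probe sets, 6.23 with the median over cells and 6.28 with the linear mean, and the pan-endothelial median was -4.96 with values set to 5, -7.48 with the median over cells and -5.09 with the linear mean. For HSC minus E12.5 cluster, the pan-endothelial median was 0.067 with the median over cells and 2.79 with the linear mean, and the G2/M median was -7.61 with the median over cells. For HSC minus E10.5 cluster, the HSC-associated median was 3.38 with quantile normalization and the erythroid median -4.61 with the linear mean.

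The erythroid median changed sign in HSC minus E10.5 cluster without a filter (0.053) and with the median over cells (0.037), and in E12.5 minus E10.5 cluster with the median over cells (0.011). Of the smaller ones, besides the blood transcription factors, in E12.5 minus E10.5 cluster the HSC-associated median of -0.28 was 0.24 with quantile normalization, 0.021 with the median over cells, 0.013 with the linear mean and 0.030 without the 6 doubted cells, and the pan-endothelial median of -0.60 was 0.011 with the median over cells. With quantile normalization Adgrg1 (0.56), Nfe2 (0.34) and Runx1 (0.61) changed sign in HSC minus E10.5 cluster. Without cross-hybridising probe sets Laptm5 did in HEC minus EC (-0.081) and cluster minus HEC (-0.045), Mcm7 in HEC minus EC (0.65) and Rbpms in E12.5 minus E10.5 cluster (0.22), since another probe set then stood for the gene. With the median over cells Gata1 did in cluster minus HEC (-0.030) and HSC minus E10.5 cluster (0.037), Klf1 in the latter (0.042) and Mcm7 in HEC minus EC (0.87). With the linear mean Cd34 (-0.69), Ifitm1 (-0.87), Lyz1 (-0.44), Lyz2 (-0.12), Myb (-0.39) and Prtn3 (-0.48) did in HSC minus E12.5 cluster. In cells with both controls at the shared value Tal1 did in cluster minus HEC (-1.51). Without the 6 doubted cells Cd34 did in HSC minus E12.5 cluster (-0.085), Mrc1 in E12.5 minus E10.5 cluster (-0.24) and Runx1 in HSC minus E10.5 cluster (0.037), the last because another probe set became the brightest.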

Other observations

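Of the tests given here, the 4 on E12.5 cluster and fetal liver cells, the one on signal over background and those on the shares of members held by 7 cluster cells were chosen after the result was seen; the one on the SD over cluster cells was not. Imprinted genes, which share Cdkn1c with the HSC-associated list, were high in EC and HEC, lower in cluster cells and higher in fetal liver HSC than in cluster cells. On average 7.71 of the 10 measured imprinted genes were above background in EC and 8.43 in HEC. Without EC cell 3 the HEC minus EC median stood at percentile 2.35 among random lists. The median difference of the imprinted genes was 1.46 for HEC minus EC (0.34 without EC cell 3, 0.49 with cells shifted to an equal median and 0.45 with quantile normalization), -5.94 for cluster minus HEC, -0.34 for E12.5 minus E10.5 cluster, 2.24 for HSC minus E12.5 cluster and 1.52 for HSC minus E10.5 cluster (2.53 with quantile normalization). Meg3, a maternally expressed non-coding RNA, was above background in 5 of 7 EC, 5 of 7 HEC, 0 of 28 and 0 of 16 cluster cells and 15 of 26 HSC. Igf2, a fetal growth factor, was found in 7 of 7 HEC, 11 of 28 E10.5 and 6 of 16 E12.5 cluster cells and 25 of 26 HSC, and Grb10, a growth inhibitor, in 7 of 7, 18 of 28, 4 of 16 and 22 of 26. In EC, Igf2 was at 11.56 or more in every cell but cell 3. Hox genes had medians of 0.95, -1.07, 0.03, 0.82 and 0.97 in the same order, the first of which was -0.02 with cells shifted to an equal median and -0.43 with quantile normalization, which gave 1.47 for each of the last 2. Hoxb3 was found in 5 of 7 HEC, 1 of 28 and 0 of 16 cluster cells and 12 of 26 HSC. Fetal programme genes had medians of 1.70, 1.05 (mean -0.63), -1.22, -1.13 and -1.92, and with quantile normalization of 0.20, 0.54, -0.58, -0.87 and -0.74. Igf2bp3, an RNA-binding protein of fetal cells, averaged 11.24 ± 1.73 in E10.5 cluster cells (27 of 28) and 5.23 ± 3.51 in HSC (10 of 26).

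MHC class I genes had lower means in EC than in HEC, with a wide spread over the EC. B2m averaged 8.90 ± 4.60 in EC (5 of 7), 13.08 ± 0.55 in HEC and 13.50 ± 0.71 in E10.5 cluster cells. On probe sets of the cross-hybridising kind, H2-K1 averaged 7.12 ± 3.58 in EC (4 of 7) and 10.22 ± 3.35 in HEC, and H2-D1 7.08 ± 4.36 (4 of 7) and 10.66 ± 3.78. The interferon and MHC list had medians of 2.5 for HEC minus EC (1.52 with cells shifted to an equal median and 0.58 with quantile normalization), 0.52, 0.10, 0.08 (mean 1.01) and 0.48 in the order above. The last 3 were 0.75, 0.93 and 1.82 with quantile normalization, with the main values at percentiles of 99.8, 99.1 and 100 among random lists, and the second fell to almost 0. Glycolysis genes had medians of 0.00, 1.03, -1.55, -1.41 and -2.96, and with quantile normalization of -0.86, 0.93, -0.84, -0.68 and -1.50, with the glucose transporter Slc2a1 at 11.67 ± 2.23 in E10.5 cluster cells and 7.75 ± 4.09 in HSC. Oxidative-phosphorylation genes had medians of 1.34, 0.69, -0.76, -1.74 and -2.44, ribosomal-protein genes 0.65, 0.54, -0.07, -0.09 and -0.44, and housekeeping genes 1.08, 0.45, -0.85, -1.37 and -2.15. With quantile normalization the oxidative-phosphorylation medians were 0.27, 0.45, -0.36, -0.52 and -0.91, the ribosomal ones -0.04, 0.24, -0.08, 0.14 and -0.02, and the housekeeping ones -0.03, -0.02, -0.23, -0.39 and -0.42. With shifted cells the first values of these lists were 0.37, -0.32 and 0.10. Dissociation-stress genes had medians of 1.86, 1.55, 0.05, -3.84 and -4.12 (1.24, 0.84, 0.86, -3.35 and -2.55 with quantile normalization), and Hspa1a, a heat-shock gene, was found in 0 of 7 EC, 2 of 7 HEC, 24 of 28 E10.5 and 13 of 16 E12.5 cluster cells and 3 of 26 HSC. Granule genes parted in HSC: Prtn3 was found in 22 of 26 HSC and Mpo in 2 of 26, while 27 of 28 E10.5 cluster cells held each of them.

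CDK-inhibitor genes had medians of 0.68 (-0.29 with cells shifted to an equal median), 0.44 (mean -0.31), 0.02, -0.44 and 0.16 (mean -0.73) in the order above, and with quantile normalization of 0.02, 0.23, 0.68, -0.33 and 0.35. Lymphoid genes had medians of 0.07, 0.88, -0.16, 0.15 and 0.05, the last 3 of which were 0.23, 0.96 and 0.76 with quantile normalization. Mesenchymal and mural genes lay between -0.48 and 0.29, hepatocyte genes between -0.32 and 0.23, and epithelial and urogenital genes between -0.82 and 0.82. Nes, the 1 measured neural-crest gene, which endothelium also expresses, differed by 1.62 for HEC minus EC (-0.39 with quantile normalization) and by -5.03 for cluster minus HEC. Germ-cell genes had 3 measured members, of which Ifitm3 is also in the interferon list, and medians of 1.45, -1.24, -0.55, 2.88 and 3.20 (1.19, -0.95, -0.15, 3.38 and 3.73 with quantile normalization). The sex-linked list had medians of 1.28, 0.58, -0.29, 0.48 and 0.23 (0.88, 0.30, 0.03, 0.66 and 0.71 with quantile normalization). Xist was above background in 3 of 7 EC, 4 of 7 HEC, 14 of 28 and 6 of 16 cluster cells and 1 of 26 HSC, a Y-linked gene in 0 of 7, 2 of 7, 12 of 28, 6 of 16 and 16 of 26, and in no cell were both.

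In 5 blood-gated cells genes of another lineage were present. E12.5 cluster cells 3, 6 and 10 had 9 of 9 measured macrophage genes above background each, against at most 4 in the other 13. C1qa was at 13.69, 13.41 and 12.32 in them. A gene counts as measured when above background in 3 cells, which these 3 can supply alone. The full 9 of 9 can therefore owe something to that filter. Cx3cr1, the unmeasured gene of the 10 on the array, was at 3.11, 11.14 and 2.34 in them. It was above background in 1 of the other 13. Macrophages that passed the E12.5 cluster gate are a candidate explanation. Macrophage RNA mixed with that of a c-Kit-positive cluster cell is argued against, since Kit reached at most 4.06 in these cells and at least 9.24 in the other 13, although the gate required c-Kit. Fetal liver HSC cells 5 and 7 had 8 and 7 venous and lymphatic genes above background, against at most 1 in the other 24, with Stab1 at 13.02 and 14.47 and Stab2 at 12.98 and 12.66, so endothelial cells that passed the fetal liver gate (the lowest number being 7) are a candidate explanation, although that gate required Sca-1, c-Kit and CD150. Endothelial RNA mixed with that of a hematopoietic stem cell is argued against, since at most 3 of 18 pan-hematopoietic genes were above background in them and at least 8 in the others; a mislabelled cell stays open, and no biological difference among cells of these gates was tested.

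The HSC-associated genes were lower in E10.5 cluster cells than in HEC (median -1.08). Lower signal over background in the cluster cells is argued against, since the median lay at percentile 0 among random lists matched on expression and cluster cells had more probe sets above background (9943 against 7712). A minority of cluster cells that holds most of the HSC-associated signal stays open: the planned test met its prediction, with an SD over cells of the number of members above background of 3.49 against a median of 2.01 for random lists (percentile 100), but the 7 of 28 cells with most members held 37.8% of all members and 52.0% of those beyond the 5 of the lowest cell, so whether they hold most depends on how members are counted. Cells 17 and 26 held 18 and 17 of the 26 members, where the median cell held 8, and also 19 and 16 of 25 pan-endothelial genes and 13 and 11 of 14 blood transcription factors, with 0 members shared between the HSC-associated and pan-endothelial lists. Differences of genotype and gate stay open, as does a pair of adhering cells.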
